A study of Rattus norvegicus with 46 samples.

How the data were processed

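RNA was measured in lung and whole blood of male Fischer 344 rats that breathed filtered air or crystalline silica dust and were killed 1 day or 6 months after the last of 5 exposure days. Per the labels' protocols, lung RNA was prepared with a kit for fibrous tissue, and blood was drawn into EDTA tubes and kept in an RNA preservative. Globin messenger RNA was then depleted from the blood RNA, and stranded libraries were made from polyadenylated RNA. The submitters' processing notes name bcl2fastq 2.19, cutadapt 3.4, Trim Galore 0.6.7, STAR 2.6.1d, Salmon 1.10.1 and the genome build Rnor_6.0, with no role or order. The annotation release is not given in the sources used here.

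The values deposited by the authors are Salmon's estimated counts per gene, not scaled to depth or gene length, in 4 tables, 1 for each tissue and time, with 30045 genes each. Salmon assigns reads that fit several transcripts by probability, so an estimated count need not be whole. Among genes named in the text, the share of samples with a count that was not whole (tolerance 1e-06) was 100% for Ltb, Hopx, Ifit1, Rrm2 and Sh2d1b2, 95.7% for Itgax, 93.5% for RT1-DMb, 89.1% for Cd79a, 87.0% for Elmod2, 65.2% for Gzmf, 60.9% for RT1-Db1, 58.7% for Ly6i, 50.0% for Mcpt9, 37.0% for RT1-Bb, 34.8% for Cd177, and 30.4% (Arntl2) or less for the others, and the level of these genes is uncertain to the extent that their reads were shared. Every column was matched to a sample by its name, and 0 columns were left unmatched. The genes keep the names in the tables, where 30045 identifiers carry 29496 names. Each identifier was tested as a gene of its own, and 266 names stand on more than 1. Among list members tested in lung these are Col1a2, Dnah5 and, at 6 months, C4a, so their lists have 1 entry more than genes. The annotation table at hand is of another assembly, so no coordinates are given.

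Estimated counts were rounded to whole numbers. Total counts were 13.4 M to 24.6 M in lung and 10.6 M to 17.5 M in blood. Before TMM scaling, 3 counts, taken as the floor for a gene with none, correspond to 0.122 to 0.282 CPM. The labels name no molecular identifiers, so floors cover counting error only. Pairs of samples within each group were compared by a chi-square test of their counts, gene by gene, over genes with a mean of at least 20 counts. A pair with under 10% of genes at p under 0.05 was counted as 1 sample, by adding its counts and halving the sum; this choice was made after seeing the data, and the fit with each such library as a separate sample stands among the alternatives. The labels do not say that the samples of a group are separate animals, and p-values measure the spread between these samples.

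Each tissue and time was tested on its own, silica against air, with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (a count of at least 10 in enough libraries and 15 in all), libraries were scaled by TMM factors, and the quasi-likelihood F test used robust dispersions. TMM factors were 0.943 to 1.03 in lung and 0.521 to 1.93 in blood. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Differences of the silica effect between times and between tissues were tested as interactions with 1 mean for each group. Overlaps of called genes were set against independent lists (Fisher's exact test, one-sided, in which genes are not independent replicates). Group levels are means ± SD of CPM, which are counts scaled to library size, and log2 fold changes carry their standard errors.

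Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. The 35 lists cover chemokines, inflammatory cytokines, acute-phase proteins, complement, interferon-stimulated and MHC class II genes, markers of neutrophils, monocytes, macrophages, giant cells, lymphocytes, mast cells and eosinophils, platelets and erythroid cells, epithelial, endothelial, ciliated and muscle genes, and lysosome, matrix, NRF2, p53, proliferation, cholesterol, tertiary lymphoid, immediate early, heat shock and clock genes. A list needed 5 tested members. The adipocyte list had fewer in each comparison and was not tested, which left 34 lists in lung. In blood 28 lists were tested at 1 day and 29 at 6 months, without the acute-phase, transitional epithelium, airway secretory, ciliated and muscle lists and, at 1 day, alveolar type 1 markers. Members not found under their names were Ccr2, Ocstamp, Tm7sf4, Cxcl15, Cfap52, Ccn2, Trp53inp1, Jchain, Hlf, Hba-a1, Hba-a2, Hba-a3 and Hbb-bs.

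The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule takes genes past the threshold with a group mean of at least 1 CPM: the 8 with the largest rise, the 8 with the largest fall and the 6 with the smallest adjusted p of the rest. Where fewer than 6 genes pass, the 5 with the smallest p are named as not passing. The rule adds 2 to 4 members of each list described, 5 genes in each direction for the differences between times or tissues, and in each comparison 10 genes that earlier work on silica in the rat lung makes relevant (Lcn2, Spp1, Ccl2, Cxcl1, Mmp12, Slc26a4, Chi3l1, Sod2, Timp1 and Col1a1). Some list members that the rule takes are not reported here; they stayed in every test and count.

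The tests were repeated with RLE factors, with no filter on low counts, with DESeq2 1.42.0, with limma and sample weights, and with a further threshold of 1.5-fold. The silica and air comparisons were also repeated with all 4 groups of a tissue in 1 fit and without the erythroid genes, every test across genes with each library left out in turn, and the tissue differences with the replicate number as a block. Chosen after seeing the data were the fit with near-identical libraries as separate samples, fits without libraries that stood apart (silica lungs 33 and 35 of 6 months, and blood libraries silica 11 of 1 day and air 25 and silica 31 of 6 months), and silica lungs of 6 months against air lungs of 1 day. Overlaps with that comparison were set against independent lists, 20 simulated sets of unchanged lungs and splits of the silica lungs. A library left out of the air lungs of 6 months leaves 1 library there, which is then taken to vary like the silica group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

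The tests were run on simulated counts in which 200 genes were changed by 1.5-, 2- or 4-fold. In lung at 1 day 67.2%, 72.2% and 91.0% of those genes were recovered at these folds, and in lung at 6 months 1.59%, 22.5% and 81.8%. In blood the shares were 14.1%, 67.9% and 97.3% at 1 day and 7.81%, 54.4% and 91.2% at 6 months. For the difference between times they were 7.35%, 45.6% and 68.0% in lung and 2.90%, 28.6% and 73.5% in blood, and for the difference between tissues 15.3%, 48.7% and 81.5% at 1 day and 2.94%, 7.35% and 46.9% at 6 months. All recovered genes had the right direction, and 0% to 8.97% of calls were false. A list raised in the simulation was recovered in each of the 8 comparisons. In the simulated lung comparison at 1 day 1 other list was called with the preset correlation and 0 with an estimated one. Genes were drawn independently of each other in the simulation. It therefore does not show how often a list is called falsely where its genes vary together.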

Results

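Gene expression was measured by RNA sequencing in lung and whole blood of aged male Fischer 344 rats after inhalation of crystalline silica (Min-U-Sil 5, a fine respirable quartz dust) or filtered air. The dust was given by whole-body inhalation at 15 mg/m3 for 6 hours a day on 5 days, and tissue was taken 1 day or 6 months later. The 46 samples fall into 8 groups of tissue, time and exposure, with 6 samples in each group except the air lungs of 6 months, which have 4. Total estimated counts were 13.4 M to 24.6 M per lung sample and 10.6 M to 17.5 M per blood sample, over 30045 genes. Between 18853 and 19780 genes had a count in a lung sample and between 14187 and 16025 in a blood sample. The 10 most abundant genes took 4.87% to 12.7% of the counts in lung and 25.4% to 46.0% in blood.

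Within the lung groups, 5 pairs of libraries differed by little more than sampling noise. Between 7.68% and 9.30% of their genes differed by a chi-square test at p under 0.05, where sampling alone gives 5%, against 21% to 73.1% in the other 46 lung pairs within a group and 24.9% to 77.6% in the blood pairs. These pairs are air 02 and 07 and air 04 and 08 at 1 day, air 19 and 24 and air 20 and 25 at 6 months, and silica 30 and 31 at 6 months. Each pair was averaged and counted as 1 sample, which leaves 41 libraries: 4 air and 6 silica lungs at 1 day, 2 air and 5 silica lungs at 6 months, and 6 of each in blood at both times. All p-values measure the spread between these libraries.

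The first comparison asked which lung genes differed from air controls 1 day after silica. Chemokine genes were among the largest rises: Ccl7, a monocyte attractant, was at 12.6 ± 2.54 CPM in silica lungs (SD, n = 6) and 0.778 ± 0.246 in air lungs (n = 4), a log2 fold change of 4.0 ± 0.22 (SE, adjusted p = 1.29e-07). The related Ccl2 was at 33 ± 5.72 against 2.95 ± 0.965 CPM (log2 fold change 3.49 ± 0.21), and Cxcl6, a neutrophil attractant, at 56.8 ± 16.6 against 4.29 ± 1.42 CPM (3.73 ± 0.33). Slc26a4, which encodes the anion exchanger pendrin, rose from 4.87 ± 1.86 to 67.7 ± 10.6 CPM (3.80 ± 0.24, adjusted p = 1.3e-05), and the chitinase-like gene Chi3l1 from 181 ± 15.3 to 571 ± 44.2 CPM (1.66 ± 0.07, adjusted p = 1.73e-08). Lcn2, which encodes an iron-siderophore-binding acute-phase protein, rose by 2.68 ± 0.16 on the log2 scale, Spp1 (osteopontin) by 3.02 ± 0.33, the macrophage elastase Mmp12 by 2.31 ± 0.35, Cxcl1 by 1.85 ± 0.21 and the mitochondrial superoxide dismutase Sod2 by 1.31 ± 0.06. Vat1l (4.56 ± 0.65), Ly6al (3.59 ± 0.22), the acute-phase gene Orm1 (3.56 ± 0.43) and the goblet cell gene Clca1 (3.55 ± 0.92, adjusted p = 0.0350) were also among the 8 largest rises. Clca1 no longer passed in 8 of the 10 fits that each left out 1 library, with the highest adjusted p of 0.0985 without air library 05. The smallest adjusted p-value belonged to Ly6i (4.02e-10), at 531 ± 15.0 CPM in silica and 160 ± 10.6 in air lungs, with an uncertain level because its estimated counts were not whole in 58.7% of the samples, as happens where reads are shared with another transcript. It was followed by Chia (1.44 ± 0.06), C4bpa (1.48 ± 0.06), Retnla (2.33 ± 0.11) and Hp, which encodes haptoglobin (1.29 ± 0.06).

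Falls in the lung at 1 day were smaller. Tac1, the precursor gene of substance P, fell by 2.65 on the log2 scale (SE 0.33, adjusted p = 0.000164), and Dlk1, a non-canonical Notch ligand, was at 12.4 ± 5.84 CPM in silica lungs (SD, n = 6) and 49.5 ± 8.36 in air lungs (n = 4; log2 fold change -1.99 ± 0.29). Alox15, an arachidonate lipoxygenase, was at 7.85 ± 1.68 against 19.7 ± 0.861 CPM (-1.33 ± 0.13, adjusted p = 3.42e-05). Car12 fell by 1.55, Kcnmb2 by 1.1, Esrrb by 1.02, Mpp4 by 0.98 and Kcnh4 by 0.87. With 1 library left out in turn, Car12 no longer passed in 8 of 10 fits (-0.66, adjusted p = 0.0932 without air library 04-08), Mpp4 in 7 and Kcnmb2 in 2 (adjusted p = 0.125 and 0.0746 without air library 02-07). The collagen gene Col1a1 (0.07 ± 0.06, adjusted p = 0.529) and the protease inhibitor gene Timp1 (0.23 ± 0.10, adjusted p = 0.194) did not pass. In all, 1836 of the 15724 genes tested passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 1196 up and 640 down, with 3848 at an unadjusted p under 0.05. Without air library 06, 1188 passed; 415 also changed at least 1.5-fold, and 594 passed when all 4 lung groups shared one fit.

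**Figure D1:**
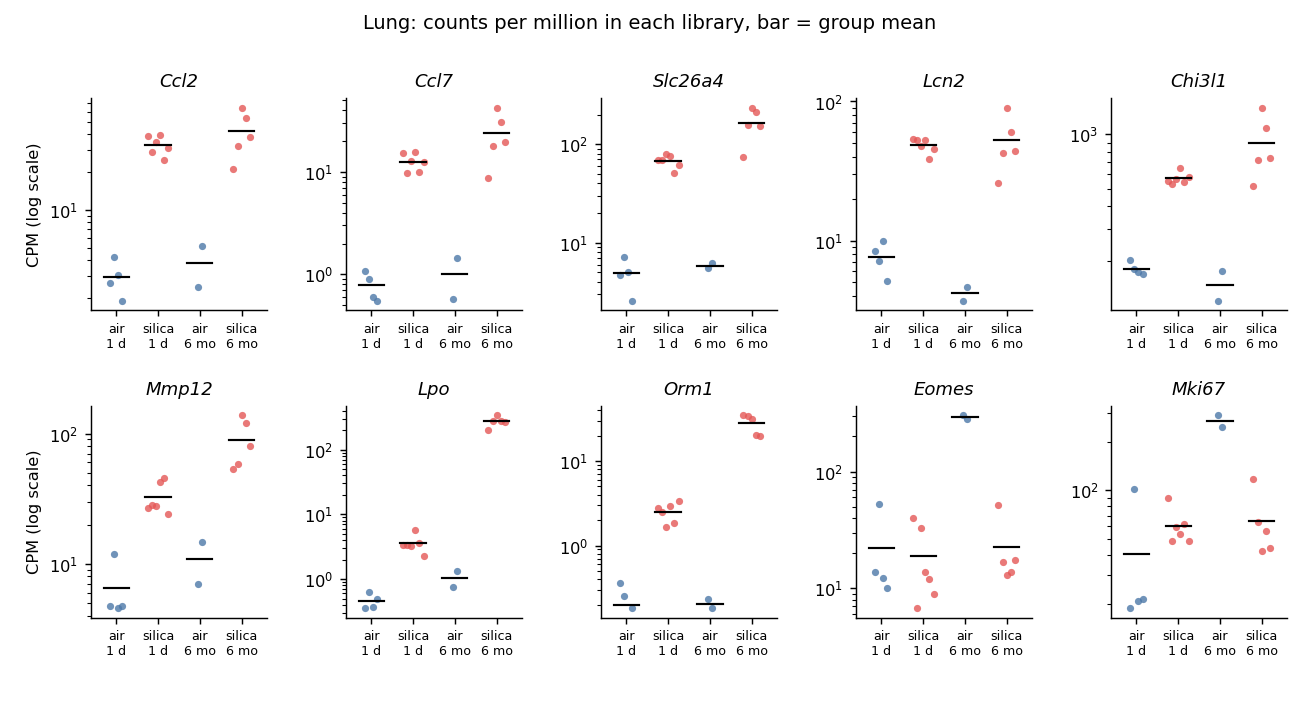
CPM (log scale) of 10 lung genes in each library, with a bar at the group mean, for 4 air and 6 silica libraries at 1 day and 2 air and 5 silica libraries at 6 months. Ccl7 means were 12.6 CPM in silica and 0.778 in air lungs at 1 day, and Lpo means were 272 and 1.04 CPM at 6 months.

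Of 34 gene lists tested in lung at 1 day, 19 passed limma's camera with its preset correlation, and the acute-phase, chemokine, complement and NRF2 lists passed with an estimated correlation as well. Of 14 acute-phase genes tested, 13 rose and none fell (13 adjusted over the list alone), with a median log2 fold change of 1.29, led by Orm1, Lcn2 and the haem-binding hemopexin gene Hpx (2.12 ± 0.12). Camera gave the list an adjusted p of 6e-18, and 0.00606 with an estimated correlation. Of 20 chemokines, 15 rose (16 adjusted over the list alone; median 1.59; camera adjusted p = 1.37e-14, and adjusted p = 0.0207 with an estimated correlation), among them Ccl22 at 3.02 ± 0.32. Complement genes rose in 13 of 15 (13 adjusted over the list alone; median 0.61), led by Cfi (1.87 ± 0.11) and C3 (1.55 ± 0.08), with a camera adjusted p of 3.74e-14 and adjusted p = 0.0207 with an estimated correlation. Of 17 oxidative stress and NRF2 genes, 11 rose (12 adjusted over the list alone; median 0.24; camera adjusted p = 5.18e-09, and adjusted p = 0.00606 with an estimated correlation), led by the cystine transporter gene Slc7a11 (1.62 ± 0.21), Sod2 and the metallothionein gene Mt2A (1.03 ± 0.25; adjusted p = 0.0651 without air library 02-07).

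The other 15 lists passed with the preset correlation alone. All 15 cholesterol synthesis genes rose (15 adjusted over the list alone), with a median of 0.65 and a camera adjusted p of 3.62e-16, led by Idi1 (1.04 ± 0.11) and Hmgcs1 (0.92 ± 0.10); the adjusted p was 0.0821 with an estimated correlation. Lysosome genes rose in 14 of 24 (17 up and 1 down adjusted over the list alone), led by Npc2 (0.69 ± 0.04) and Ctsz (0.64 ± 0.05). Lysosome genes as a list had adjusted p = 0.0902 with an estimated correlation. In the lipid-associated macrophage list, Spp1, Mmp12, Chi3l1 and Ctsk (1.11 ± 0.12) led 11 rises and 2 falls among 19 genes (15 and 2 adjusted over the list alone), adjusted p = 0.0902 with an estimated correlation. Alveolar macrophage markers rose in 8 of 16 and fell in 2 (9 and 2 adjusted over the list alone), led by Atp6v0d2 (1.72 ± 0.11) and the lysosomal Cd68 (0.95 ± 0.05). Alveolar macrophage markers as a list had adjusted p = 0.135 with an estimated correlation. Giant cell and osteoclast genes gave 4 rises and 1 fall among 8 (also 4 and 1 adjusted over the list alone), led by Atp6v0d2 and the osteoclast protease gene Ctsk. Giant cell and osteoclast genes as a list had adjusted p = 0.11 with an estimated correlation. Neutrophil markers gave 8 rises and 1 fall among 15 (8 and 1 adjusted over the list alone), led by Cd177 (2.18 ± 0.12) and S100a9 (1.90 ± 0.14). Neutrophil markers as a list had adjusted p = 0.158 with an estimated correlation. Inflammatory cytokine genes gave 9 rises and 1 fall among 15 (9 and 1 adjusted over the list alone), led by Il1r2, which encodes the interleukin-1 decoy receptor (1.88 ± 0.12), and Csf2 (1.07 ± 0.25). Inflammatory cytokine genes as a list had adjusted p = 0.0992 with an estimated correlation. MHC class II genes rose in 7 of 10 (7 adjusted over the list alone), led by RT1-DMb (0.56 ± 0.13; adjusted p = 0.0641 without air library 06) and RT1-Bb (0.44 ± 0.06). MHC class II genes as a list had adjusted p = 0.161 with an estimated correlation. Monocyte markers rose in 4 of 12 (4 up and 1 down adjusted over the list alone), led by Cd14 (0.45 ± 0.05) and Vcan (0.44 ± 0.12; adjusted p = 0.0955 without air library 06). Monocyte markers as a list had adjusted p = 0.301 with an estimated correlation. The camera adjusted p of the monocyte list was 0.154 without air library 04-08, 0.0541 without silica library 13 and 0.0716 without silica library 14.

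Epithelial and endothelial lists moved in different directions at 1 day. Alveolar type 2 cell and surfactant genes rose in 10 of 15 (10 up and 1 down adjusted over the list alone; median 0.23), led by the surfactant protein genes Sftpa1 (0.70 ± 0.06) and Sftpd (0.54 ± 0.06). Alveolar type 2 cell and surfactant genes as a list had adjusted p = 0.158 with an estimated correlation. Airway secretory genes rose in 5 of 12 (6 adjusted over the list alone), led by Slc26a4, Clca1 and Bpifb1 (3.06 ± 0.37). Airway secretory genes as a list had adjusted p = 0.203 with an estimated correlation. Alveolar type 1 cell markers fell in 5 of 13 (5 adjusted over the list alone; median -0.12), led by Igfbp2 (-0.55 ± 0.11) and Hopx (-0.36 ± 0.06). Over the list alone, 10 type 1 markers fell without air library 05 or silica library 11 and 8 without air library 02-07. Alveolar type 1 cell markers as a list had adjusted p = 0.127 with an estimated correlation. Endothelial markers fell in 7 of 13 (10 adjusted over the list alone; median -0.20), led by the tight junction gene Cldn5 (-0.43 ± 0.08) and Plvap (-0.33 ± 0.07; adjusted p = 0.0516 without air library 06). Without air library 06, 2 of the 13 endothelial markers passed. Endothelial markers as a list had adjusted p = 0.158 with an estimated correlation. Tertiary lymphoid tissue genes rose in 2 of 9, Ltb (0.85 ± 0.07) and Ccr7 (0.57 ± 0.15; adjusted p = 0.0920 without air library 05), with 5 adjusted over the list alone (2 without air library 04-08, and 3 without air library 05 or 06 or silica library 12) and adjusted p = 0.161 with an estimated correlation. Proliferation genes were higher as a list (median 0.52, camera adjusted p = 5.54e-05, adjusted p = 0.482 with an estimated correlation), but none of the 21 passed, over all genes or adjusted over the list alone; Rrm2 was at 1.07 ± 0.34. Air library 04-08 had a mean log2 CPM of 3.59 over the proliferation genes, against 1.88 to 2.09 in the other 3 air lungs and 2.93 to 3.50 in the silica lungs. Without it, 17 of the 21 rose (19 adjusted over the list alone; median 1.42), with Rrm2 at 1.66. In the fits that left out any other library, none of the 21 passed.

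Of the lists that did not pass at 1 day, extracellular matrix genes rose in 5 of 22 entries for 21 genes (5 adjusted over the list alone; camera adjusted p = 0.0670), among them Cthrc1 (0.85 ± 0.18) and Tnc (0.46 ± 0.13). Col1a2, named after its values were seen, has 2 entries, of which 1 is among the 5 (0.21 ± 0.05) and the other was at -0.07 ± 0.07. With any 1 library left out, 1 to 3 matrix entries passed (1 to 7 adjusted over the list alone). Interferon-stimulated genes rose in 2 of 21 (3 adjusted over the list alone, 0 to 5 with each library left out; camera adjusted p = 0.0780), Ifit1 (1.04 ± 0.23) and Oasl2 (0.25 ± 0.08). Tnc no longer passed with RLE factors, with no filter on low counts or with all 4 groups in 1 fit, nor in 7 of the 10 fits that each left out 1 library (adjusted p = 0.153 without air library 02-07), and Oasl2 in 8 (0.138 without air library 05). None of the 16 NK and large granular lymphocyte markers passed, over all genes or adjusted over the list alone (median -0.19, camera adjusted p = 0.443). B cell (median -0.12), T cell (0.01), mast cell and eosinophil (0.08), platelet (0.09), erythroid (-0.24), alveolar transitional epithelium (0.05), p53 target (0.08), heat shock (-0.01), immediate early (0.33) and cardiac and skeletal muscle (0.66) lists had camera adjusted p-values from 0.245 to 0.855. The circadian clock list had a positive median (0.01) where camera's direction was down (adjusted p = 0.779), and the ciliated cell list a positive median (0.02) where its mean and camera's direction were negative (adjusted p = 0.792).

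The next comparison asked which lung genes differed 6 months after exposure. Lpo, which encodes the airway enzyme lactoperoxidase, was at 272 ± 48.6 CPM in silica lungs (SD, n = 5) and 1.04 ± 0.403 in air lungs (n = 2), a log2 fold change of 8.0 ± 0.36 (SE, adjusted p = 0.000413). Orm1 was at 27.9 ± 7.44 against 0.207 ± 0.0345 CPM (7.05 ± 0.46, adjusted p = 0.00284), Slc26a4 at 166 ± 62.3 against 5.87 ± 0.461 CPM (4.82 ± 0.52, adjusted p = 0.00481) and Cxcl6 at 65.4 ± 18.0 against 2.40 ± 0.211 CPM (4.76 ± 0.37). Vat1l (6.40 ± 0.57), Retnla (5.65 ± 1.08), Slc3a1 (5.03 ± 1.18) and the acidic chitinase gene Chia (4.77 ± 0.57) complete the 8 largest rises, and Tmem45b (4.65 ± 0.37) had one of the smallest p-values. Lcn2 rose by 3.65 ± 0.53 on the log2 scale, Ccl2 by 3.44 ± 0.55, Mmp12 by 3.05 ± 0.53, Spp1 by 2.62 ± 0.64, Chi3l1 by 2.6 ± 0.44, Cxcl1 by 2.10 ± 0.26, Sod2 by 1.70 ± 0.25 and Timp1 by 1.01 ± 0.26 (adjusted p = 0.0327), while Col1a1 did not pass (0.30 ± 0.25, adjusted p = 0.442). The largest falls were in Arl14epl (-5.58 ± 0.76), Mepe (-5.27 ± 0.93), the claudin gene Cldn20 (-5.10 ± 0.52; 0.0921 ± 0.0638 against 3.42 ± 0.0663 CPM), Arntl2 (-5.09 ± 1.00), Tdrd1 (-5.06 ± 0.70), Plb1 (-4.68 ± 0.46), the granzyme gene Gzmf (-4.23 ± 0.69, adjusted p = 0.00911) and Shank1 (-4.03 ± 0.91). Mier2 was at 15.5 ± 2.71 against 94.3 ± 17.4 CPM (-2.6 ± 0.18, adjusted p = 0.00284), and Galnt6 (-1.90 ± 0.14), Tmem200c (-2.51 ± 0.19), Aim1l (-1.67 ± 0.13) and Scn3b (-1.93 ± 0.16) were among the smallest p-values.

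Of 16267 lung genes tested at 6 months, 3189 passed, 1547 up and 1642 down, with 5575 at an unadjusted p under 0.05 (3001 without air library 19-24). The air group holds 2 libraries, and the count rests on both: 56 genes passed without air library 19-24 and 1063 without air library 20-25, where the lone air library was taken to vary like the silica group, and 1758 and 1748 passed without silica library 34 or 35. Of 79 genes named in this comparison, 46 passed without air library 20-25, 61 without silica library 34, 61 without silica library 35 and 70 without silica library 32. The 13 that passed without air library 19-24 were Lpo, Orm1, Vat1l, Cxcl6, Tmem45b, Fcer2, Mier2, Galnt6, Tmem200c, Aim1l, Scn3b, Plb1 and Cldn20, and Gzmf was then at -2.70. Of the gene lists, chemokines had 2 members past the threshold without air library 19-24, acute-phase and tertiary lymphoid genes 1 each, and the others 0. Over the 34 lists together, 240 of 499 members passed, with a gene counted in each list that holds it, and 284 adjusted over the list alone. Those sums were 4 and 165 without air library 19-24, 98 and 243 without air library 20-25, and 162 and 255 without silica library 35. Both air lungs stood apart from the other lung libraries in lymphocyte genes. Their mean log2 CPM over the NK and large granular lymphocyte markers was 6.30 and 6.25, against 3.31 to 5.32 in the other 15 lung libraries, and over the proliferation genes it was 4.55 and 4.52 against 1.88 to 3.74. In an added comparison, chosen after seeing the data, the silica lungs of 6 months were set against the 4 air lungs of 1 day. Each time is a table of its own, so silica, time after exposure, age and batch cannot be told apart in values against those lungs. This limit holds wherever the air lungs of 1 day serve as the reference below. Of the 1547 rises, 833 passed upward there too, and 68 of the 1642 falls passed downward. The air lungs of 6 months themselves differed from those of 1 day: 992 of the 1547 genes passed as lower at 6 months and 1574 of the 1642 as higher. Since each of these comparisons shares libraries with the calls it is set against, part of the overlap is built in. Independent lists give 217 rises and 201 falls for the silica lungs and 297 and 376 for the air lungs. In 20 simulated sets of unchanged lungs at most 1 gene per direction was called between silica and air at 6 months, so they do not show how much overlap the shared libraries build in. The silica lungs were then split so that no silica library of 6 months entered both comparisons. Of 10 splits, 7 had at least 100 calls in each direction. In these, 32.6% to 60.4% of the rises and 1.07% to 19.2% of the falls passed the same way. The 2 air lungs of 6 months were not split, and part of the excess may come from sharing them. In the fits against the air lungs of 1 day they entered the filter, scaling and spread but not the contrast. Lpo, Orm1 and Slc26a4 passed upward against the air lungs of 1 day at 9.19, 7.05 and 5.12. Mier2, Gzmf, Plb1, Arl14epl, Mepe, Tdrd1, Galnt6, Aim1l and Scn3b, named above as falls, had positive values there, from 0.11 (Arl14epl) to 1.74 (Mepe). Of these, Galnt6 alone passed (0.55). Arntl2 (-0.22), Cldn20 (-0.21), Shank1 (-1.49) and Tmem200c (-0.30), the other falls named above, had negative values that did not pass there.

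**Figure D2:**
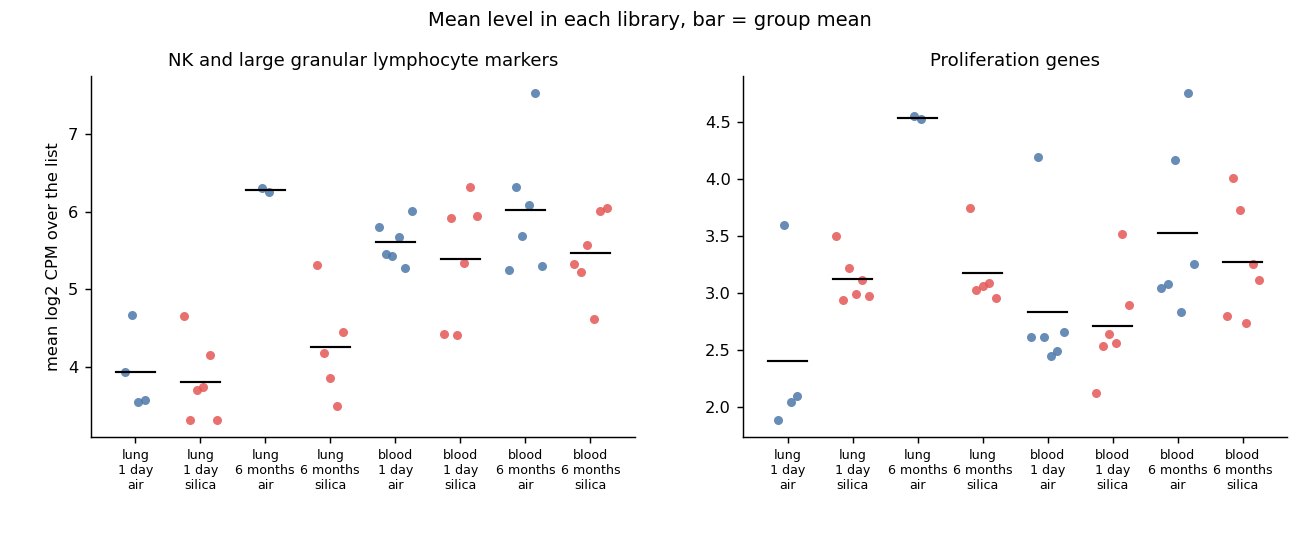
Mean log2 CPM over the NK and large granular lymphocyte markers (left) and the proliferation genes (right) in each library, with a bar at the group mean. The 2 air lungs of 6 months lie at 6.30 and 6.25 for the lymphocyte markers, above every other lung library, and the highest blood library is air 25 of 6 months at 7.53.

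At 6 months, 23 lists passed camera in lung with the preset correlation, and none with an estimated one. Of 16 NK and large granular lymphocyte markers, 12 fell (14 adjusted over the list alone; median -2.32; camera adjusted p = 1.97e-07), led by the transcription factor Eomes (-3.70 ± 0.51), Nkg7 (-2.97 ± 0.41) and the perforin gene Prf1 (-2.85 ± 0.44). NK and large granular lymphocyte markers as a list had adjusted p = 0.246 with an estimated correlation. Proliferation genes fell in 18 of 21 (21 adjusted over the list alone; median -1.54; camera adjusted p = 4.12e-11), led by Top2a (-2.24 ± 0.44), Kif11 (-2.22 ± 0.33) and Mki67 (-2.05 ± 0.36). Proliferation genes as a list had adjusted p = 0.237 with an estimated correlation. Against the air lungs of 1 day, the medians of these lists in the silica lungs of 6 months were 0.36 and 0.65. T cell markers rose in 10 of 16 and fell in 3 (11 and 3 adjusted over the list alone), with the regulatory T cell genes Ctla4 (2.99 ± 0.43) and Foxp3 (2.82 ± 0.35) up and Cd8a (-2.55 ± 0.50) down. T cell markers as a list had adjusted p = 0.237 with an estimated correlation. B cell and plasma cell markers rose in 7 of 14 and fell in 1 (10 and 1 adjusted over the list alone), led by Tnfrsf17 (3.05 ± 0.65) and Mzb1 (2.94 ± 0.52). B cell and plasma cell markers as a list had adjusted p = 0.229 with an estimated correlation. Tertiary lymphoid tissue genes rose in 6 of 10 (8 adjusted over the list alone), among them Fcer2 (3.15 ± 0.26) and Ccr7 (2.32 ± 0.36). Tertiary lymphoid tissue genes as a list had adjusted p = 0.229 with an estimated correlation. Against the air lungs of 1 day, the T cell, B cell and tertiary lymphoid medians were 0.57, -0.30 and 0.73, and Cd8a, at 1.03, did not pass. Of the member genes named here, Fcer2 alone passed without air library 19-24 (adjusted p = 0.0448). Over the list alone, 6 B cell markers and 5 tertiary lymphoid genes then rose.

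Inflammatory and myeloid lists rose in the lung at 6 months against air lungs with the high lymphocyte marker levels given above. Acute-phase genes rose in 13 of 14 (14 adjusted over the list alone; median 1.79; camera adjusted p = 3.55e-09), led by Orm1 and Lcn2. Acute-phase genes as a list had adjusted p = 0.229 with an estimated correlation. Complement genes rose in 12 of 16 entries for 15 genes, since C4a has 2 (15 adjusted over the list alone; median 1.31), led by Cfi (3.12 ± 0.51) and C3 (2.69 ± 0.32). Complement genes as a list had adjusted p = 0.229 with an estimated correlation. Neutrophil markers rose in 9 of 15 (11 adjusted over the list alone; median 1.72), led by the calprotectin genes S100a9 (4.52 ± 0.64) and S100a8 (3.73 ± 0.61). Neutrophil markers as a list had adjusted p = 0.229 with an estimated correlation. Chemokines rose in 11 of 20 and fell in 2 (12 and 2 adjusted over the list alone; median 1.69), led by Cxcl6, Ccl7 (4.51 ± 0.76) and Cxcl11 (4.49 ± 1.18). Chemokines as a list had adjusted p = 0.246 with an estimated correlation. Lipid-associated macrophage genes rose in 16 of 19 (17 adjusted over the list alone, median 1.29), led by Mmp12 and Spp1. Without silica library 34 or 35, 5 of the 19 passed (17 adjusted over the list alone). Lipid-associated macrophage genes as a list had adjusted p = 0.271 with an estimated correlation. Alveolar macrophage markers rose in 9 of 17 and fell in 1 (11 and 1 adjusted over the list alone), with the lipid-binding Fabp4 at 3.03 ± 0.68 and the integrin gene Itgax at -2.09 ± 0.33. Alveolar macrophage markers as a list had adjusted p = 0.246 with an estimated correlation. Mast cell, basophil and eosinophil markers rose in 6 of 10 (8 adjusted over the list alone; median 1.94), led by the IgE receptor gene Fcer1a (2.46 ± 0.51) and the mast cell protease gene Cpa3 (2.26 ± 0.60). Mast cell, basophil and eosinophil markers as a list had adjusted p = 0.246 with an estimated correlation. Inflammatory cytokine genes rose in 6 of 15 and fell in 2 (10 and 2 adjusted over the list alone), with Il1r2 at 3.4 ± 0.51, Il1b at 2.42 ± 0.23 and the inflammasome adaptor Pycard at -1.76 ± 0.21. Inflammatory cytokine genes as a list had adjusted p = 0.229 with an estimated correlation. MHC class II genes rose in 9 of 10 (9 adjusted over the list alone), led by RT1-Db1 (1.74 ± 0.41) and RT1-DOa (1.70 ± 0.35). MHC class II genes as a list had adjusted p = 0.246 with an estimated correlation. Monocyte markers rose in 8 of 12 (8 adjusted over the list alone), led by Fcnb (2.16 ± 0.26) and Ms4a7 (1.71 ± 0.38). Monocyte markers as a list had adjusted p = 0.229 with an estimated correlation. Against the air lungs of 1 day, the list medians were 1.8 for acute-phase genes, 1.03 for complement, 0.79 for neutrophil markers, 1.45 for chemokines, 0.77 for lipid-associated macrophage genes, 0.86 for alveolar macrophage markers, 1.86 for mast cell markers, 0.64 for cytokine genes, 1.05 for MHC class II genes and 0.36 for monocyte markers. Itgax was at 1.13 and Pycard at 0.64 there. Between the air lungs of 1 day and 6 months, 9 of 15 neutrophil markers fell and 2 rose (median -0.79). Of the member genes named here, Orm1 and Cxcl6 alone passed without air library 19-24 (adjusted p = 0.0375 and 0.0448), and Cxcl11 was at 9.43 without air library 20-25 (adjusted p = 0.0666). Without air library 19-24, the rises over the list alone were 6 for cytokine genes, 5 for lipid-associated macrophage genes, 2 each for alveolar macrophage and mast cell markers and 1 for monocyte markers.

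Among lung pathways and structural cells at 6 months, lysosome genes rose in 15 of 24 (20 adjusted over the list alone, median 0.71). They were led by the cathepsin gene Ctsz (1.61 ± 0.39) and the sterol transporter gene Npc2 (1.60 ± 0.38), and camera gave the list an adjusted p of 0.259 with an estimated correlation. Without silica library 34 or 35, 3 of the 24 passed (16 adjusted over the list alone), and without silica library 32, 8 (19). Oxidative stress and NRF2 genes rose in 10 of 17 (10 up and 1 down adjusted over the list alone), led by Slc7a11 (2.62 ± 0.48) and Srxn1 (1.82 ± 0.26). Oxidative stress and NRF2 genes as a list had adjusted p = 0.229 with an estimated correlation. Alveolar type 2 cell genes rose in 12 of 15 (14 adjusted over the list alone; median 1.1), led by Sftpd (1.75 ± 0.38) and Sftpa1 (1.63 ± 0.35). Alveolar type 2 cell genes as a list had adjusted p = 0.237 with an estimated correlation. Alveolar transitional epithelium genes rose in 5 of 13 (9 adjusted over the list alone), led by the EGF receptor ligand gene Areg (2.17 ± 0.58) and the galectin gene Lgals3 (1.51 ± 0.38). Alveolar transitional epithelium genes as a list had adjusted p = 0.237 with an estimated correlation. Platelet markers rose in 3 of 9 (3 adjusted over the list alone), led by Pf4 (1.18 ± 0.29) and P2ry12 (1.06 ± 0.28). Platelet markers as a list had adjusted p = 0.229 with an estimated correlation. Airway secretory genes rose in 4 of 12 (4 adjusted over the list alone), led by Slc26a4 and Bpifb1 (3.37 ± 0.92), with a camera adjusted p of 0.00858, 0.842 without air library 19-24, and adjusted p = 0.486 with an estimated correlation. The ciliated cell list passed with none of the 17 entries for its 16 genes past the threshold, over all genes or adjusted over the list alone (5 and 8 without air library 20-25; camera adjusted p = 0.0256, 0.925 without air library 19-24, and adjusted p = 0.552 with an estimated correlation). Alveolar type 1 cell markers rose in 2 of 13, Gprc5a (0.63 ± 0.14) and Pdpn (0.56 ± 0.14), with 4 adjusted over the list alone; the camera adjusted p was 0.0488. Alveolar type 1 cell markers as a list had adjusted p = 0.237 with an estimated correlation. The type 1 list no longer passed in 6 of the 7 fits that each left out 1 library (0.0931 without air library 20-25), and the ciliated list had 0.0889 without silica library 30-31. Against the air lungs of 1 day, Gprc5a was at -0.25 and Pdpn at -0.22, and the type 1, platelet and ciliated medians were -0.39, -0.45 and -0.14. The other medians there were 0.49 for type 2 cell genes, 0.46 for lysosome, 0.56 for NRF2, 0.45 for transitional epithelium and 0.90 for airway secretory genes. Between the air lungs of 1 day and 6 months, 11 of 15 type 2 genes, 10 of 13 type 1 markers and 6 of 10 platelet markers fell. None of the member genes named here passed without air library 19-24, and Bpifb1 was at 5.15 without air library 20-25 (adjusted p = 0.0567). Over the list alone, lysosome genes had 0 rises without air library 19-24 and 12 without air library 20-25, and transitional epithelium and type 1 lists 0 without either. NRF2 genes had 5 rises and platelet markers 0 without air library 19-24. Airway secretory genes had 2 rises and 3 falls without air library 19-24 and 10 rises without air library 20-25. Type 1 markers also had 0 without silica library 34 or 35 and 7 without silica library 33.

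Cholesterol synthesis genes, which all rose at 1 day, split at 6 months: 2 rose and 3 fell of 15 (2 and 5 adjusted over the list alone; median -0.15; camera adjusted p = 0.134), with Hmgcs1 at -0.91 ± 0.11 and Sqle at 0.60 ± 0.17. In air lungs 9 of the 15 rose and 1 fell from 1 day to 6 months (median 0.55), and against the air lungs of 1 day the silica lungs of 6 months had a median of 0.28, with Hmgcs1 at 0.30 (adjusted p = 0.0299). Extracellular matrix genes gave 2 rises and 1 fall in the 22 entries for 21 genes (2 and 1 adjusted over the list alone; camera adjusted p = 0.199), with Timp1 at 1.01 ± 0.26 and Tgfb1 at -0.63 ± 0.14 (0.50 against the air lungs of 1 day). Interferon-stimulated genes gave 2 rises and 1 fall of 21 (2 and 1 adjusted over the list alone; camera adjusted p = 0.371), with Ifit1 at 3.44 ± 0.50 and Ifit3 at 1.93 ± 0.34. The 5 falls of cholesterol genes over the list alone were 2 without either air library or silica library 30-31, 32, 34 or 35. Interferon-stimulated genes had 5 rises (6 adjusted over the list alone) without silica library 30-31. None of these member genes passed without air library 19-24, where Hmgcs1 had an adjusted p of 0.0669. Giant cell genes (camera adjusted p = 0.0808), erythroid genes (0.101), p53 targets (0.485), clock genes (0.485) and endothelial markers (0.522) did not pass. The cardiac muscle and immediate early lists had negative medians (-0.44 and -0.22), and the heat shock list a negative median (-0.08) with a positive mean, where camera's direction was up in each (adjusted p = 0.689, 0.910 and 0.911).

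**Figure D3:**
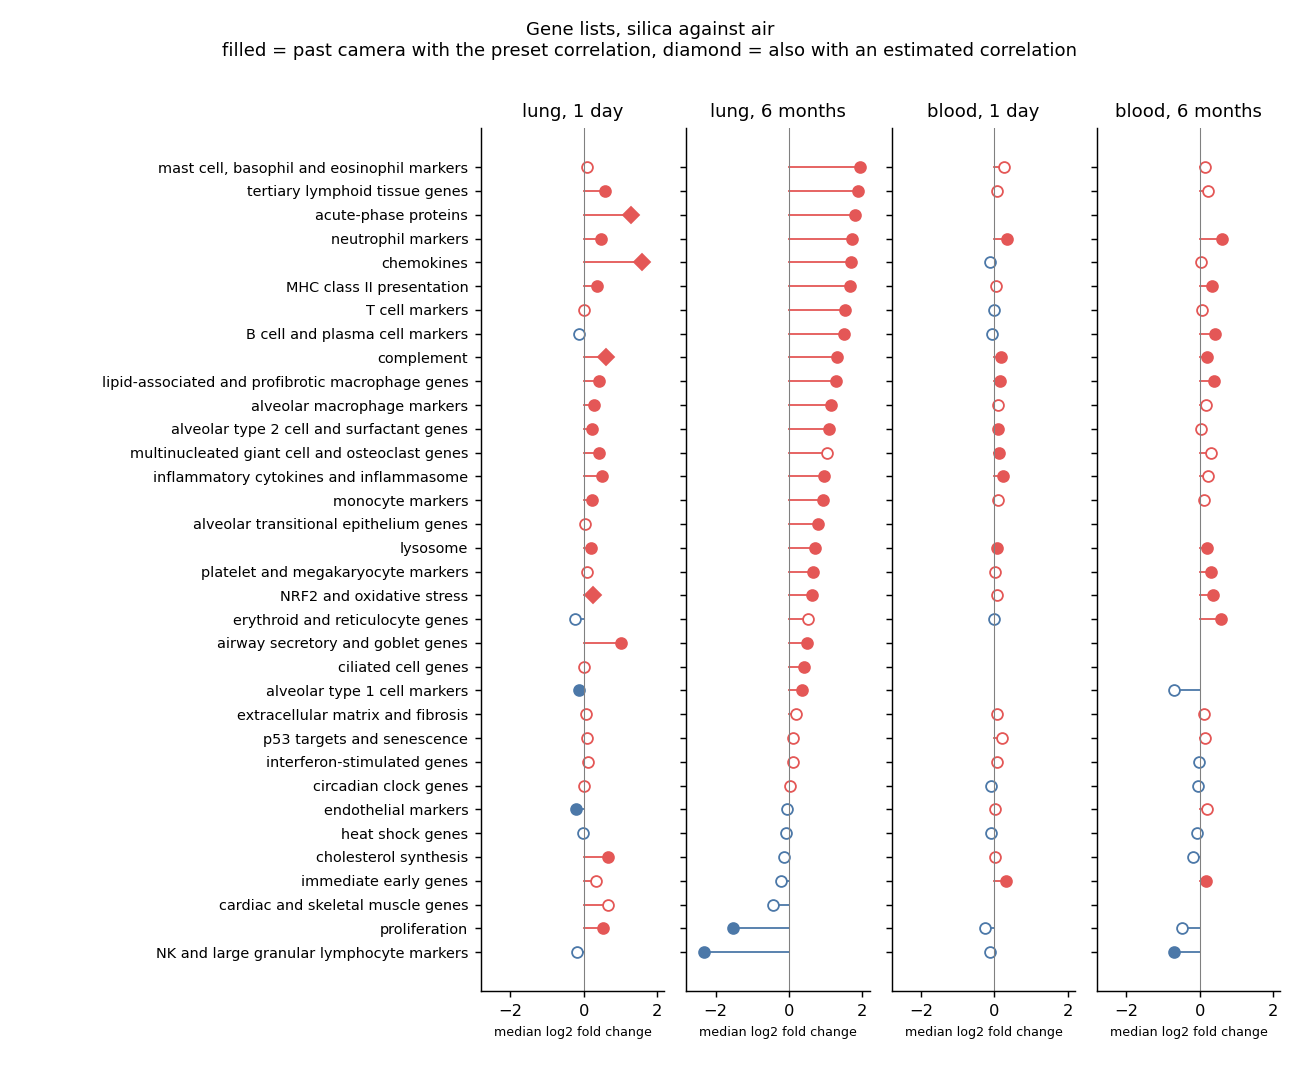
Median log2 fold change of silica over air for each gene list in the 4 comparisons, with filled markers where limma's camera passed an adjusted p of 0.05 with its preset correlation and diamonds where it also passed with an estimated one. Diamonds appear for 4 lists in lung at 1 day, and the lowest median is that of the NK and large granular lymphocyte markers in lung at 6 months (-2.32).

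Blood was compared at the same times to ask whether the circulation carried a response. At 1 day no blood gene of the 11876 tested passed by edgeR's quasi-likelihood test, DESeq2 or limma with sample weights. EdgeR gave 430 genes at an unadjusted p under 0.05. That count was 1094 without silica library 11 and 255, 274 and 284 without air libraries 05, 02 and 04. The smallest p-values belonged to Elmod2 (log2 fold change -1.64 ± 0.36), the 5-lipoxygenase gene Alox5 (0.56 ± 0.13; 23.6 ± 2.32 against 16 ± 2.73 CPM, SD, n = 6 each), the neutrophil granule gene Pglyrp1 (0.77 ± 0.19), Them4 (-1.02 ± 0.26) and Pygl (0.43 ± 0.12), each with an adjusted p of 1. Chi3l1 was at 577 ± 98.9 CPM in silica and 428 ± 68.5 in air blood (0.43 ± 0.15, adjusted p of 1). Neutrophil markers were higher as a list (median 0.36, camera adjusted p = 3.01e-06), with 0 of 15 past the threshold and 2 adjusted over the list alone, and adjusted p = 0.282 with an estimated correlation. The count over the list alone was 0 to 8 with each library left out, and 8 without silica library 11. Immediate early genes (median 0.32, camera adjusted p = 1.99e-05, adjusted p = 0.282 with an estimated correlation) were led by Junb (0.65 ± 0.24; 0.35 without silica library 11), with none past the threshold over all genes or adjusted over the list alone. The lipid-associated macrophage, inflammatory cytokine, complement, giant cell, alveolar type 2 and lysosome lists were also higher by camera (adjusted p from 0.00093 to 0.0354), and none of the 8 lists passed with an estimated correlation (adjusted p from 0.282 to 0.338). One silica library, replicate 11, lay apart on the first principal component, which held 44.7% of the variance; without it the alveolar type 2 and giant cell lists no longer passed (adjusted p = 0.258 and 0.458). The lysosome and complement lists had an adjusted p of 0.127 without air library 04, the lysosome list 0.118 without air library 05 and 0.0878 without silica library 16, the alveolar type 2 list 0.0844 without air library 02 and the cytokine list 0.0598 without silica library 12.

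At 6 months no blood gene of the 11615 tested passed by edgeR, with 720 at an unadjusted p under 0.05. That count was 1119 without air library 19 and 416 without silica library 33. DESeq2 gave 7 genes and limma with sample weights 5, which were Ifitm6, Far1, Sytl2, LOC102550484 and LOC103689945. Of the 7 by DESeq2, Aph1b and Eif3h had fitted log2 fold changes of 24.2 and 24.1, which are not read as sizes of an effect. The others ranged in absolute value from 0.46 (Far1) to 8.14 (Nol8, at -8.14). Without air library 19, Ifitm6 and Nol8 passed by edgeR, and without silica library 36, LOC103689945; these names were chosen after their values were seen. The smallest p belonged to Ifitm6, an interferon-induced transmembrane protein gene, at 8.08 ± 1.94 CPM in silica and 3.36 ± 1.00 in air blood (SD, n = 6 each; log2 fold change 1.26 ± 0.21, adjusted p = 0.446). Far1 (0.46 ± 0.10), Galnt3 (0.93 ± 0.23), Neurl4 (-0.50 ± 0.12) and Tmed4 (-0.61 ± 0.15) followed, at an adjusted p of 0.658. Neutrophil markers were again higher as a list (median 0.62, camera adjusted p = 5.17e-10), with Mmp8 at 0.80 ± 0.22 and the granule gene Ngp at 0.88 ± 0.25; 0 of 14 passed over all genes and 8 adjusted over the list alone, with adjusted p = 0.593 with an estimated correlation. The count of 8 was 0 without air library 25 or silica library 32 or 33, 3 without air library 21 and 4 without air library 20. It was 5 without silica library 34. NK and large granular lymphocyte markers were lower (median -0.69, camera adjusted p = 0.0122, adjusted p = 0.593 with an estimated correlation), with Eomes at -1.63 ± 0.66 (-0.25 without air library 25), none past the threshold over all genes or adjusted over the list alone. That list had its highest level in air library 25, at a mean log2 CPM of 7.53 against at most 6.32 in any other blood library, and without it the adjusted p was 0.232. Of the 11 lists that passed camera, none passed with an estimated correlation, and the neutrophil list alone passed in all 12 fits that each left out 1 library. Erythroid genes (median 0.58), platelet markers (0.31), B cell markers (0.42) and MHC class II genes (0.33) had camera adjusted p-values from 0.00124 to 0.00719, each at adjusted p = 0.593 with an estimated correlation, and from 0.135 to 0.295 without air library 25. Leaving out air library 19 or 21, or silica library 30, 31, 32, 33, 34 or 36, also ended 1 to 4 of the 11 calls, among them erythroid genes without silica library 31 (adjusted p = 0.0780) and NK markers without silica library 33 (0.0707).

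Whether the silica effect in lung differed between 1 day and 6 months was tested as an interaction. Of 16567 genes, 4436 passed, 2012 with a more positive effect at 6 months and 2424 with a more negative one. The difference was 5.03 ± 0.59 on the log2 scale for Lpo (SE, adjusted p = 0.000111), which was at 3.55 ± 1.15 CPM in silica and 0.460 ± 0.129 in air lungs at 1 day (SD, n = 6 and 4). It was 3.46 ± 0.77 for Orm1, 3.66 ± 1.1 for the acid-sensing channel gene Asic2 and 3.49 ± 1.06 for Klri2, a killer lectin-like receptor gene. The B cell receptor gene Cd79a (adjusted p = 0.00905) was at 0 counts in both air lungs of 6 months and at 0.481 ± 0.421 CPM in silica lungs (n = 5), so its fitted fold sets no bound. The most negative differences were in Wnt10b (-7.45 ± 1.86), Proz, whose counts were 0 in the air lungs of 1 day (adjusted p = 0.0154), Arl14epl (-6.58 ± 1.14), Fam19a4 (-6.55 ± 1.59) and Gzmf (-6.18 ± 1.45), genes with 1.60 to 9.25 CPM in the air lungs of 6 months. Of the sentinel genes, Timp1 alone passed (0.75 ± 0.25, adjusted p = 0.0374), while Ccl2 (-0.07 ± 0.50), Cxcl1 (0.23 ± 0.32), Mmp12 (0.71 ± 0.58), Spp1 (-0.43 ± 0.69), Lcn2 (0.95 ± 0.46) and Chi3l1 (0.91 ± 0.34, adjusted p = 0.0552) did not. Cholesterol synthesis genes had a more negative effect at 6 months in 10 of 15 (11 adjusted over the list alone; median -0.80; camera adjusted p = 3.23e-07). Cholesterol synthesis genes as a list had adjusted p = 0.128 with an estimated correlation. From 1 day to 6 months, 9 of these 15 genes rose and 1 fell in air lungs (median 0.55), and 8 fell in silica lungs (median -0.33). Without air library 19-24 of 6 months, 1642 genes passed, and Asic2, Cd79a, Gzmf, Klri2, Proz and Timp1 did not (adjusted p from 0.0571 to 0.209). Klri2 and Timp1 did not pass without air library 20-25 either (0.13 for Klri2), Timp1 no longer passed in 7 of the 17 fits that each left out 1 library, and Wnt10b was at -4.68 without silica library 10 of 1 day.

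The genes called in lung at both times overlapped upward. Of 15655 genes tested at both, 550 rose at both times, against 114 for independent lists of 1196 and 1497 genes, and 25 fell at both, against 61.8 for lists of 636 and 1522. Another 59 rose at 1 day and fell at 6 months, where independent lists give 116, and 46 fell and then rose, where they give 60.8. No library entered both comparisons. The calls at 6 months, and so this overlap, rest on both air lungs of that time, as given above. Vat1l, Ccl7, Slc26a4, Orm1, Retnla and Chia rose at both times, and Hmgcs1 and Idi1 rose at 1 day and fell at 6 months (Idi1 by 0.37). Against the air lungs of 1 day both were higher in the silica lungs of 6 months (0.30 and 0.68), and the fall of Idi1 no longer passed in 6 of the 7 fits that each left out 1 library (adjusted p = 0.406 without air library 19-24).

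**Figure D4:**
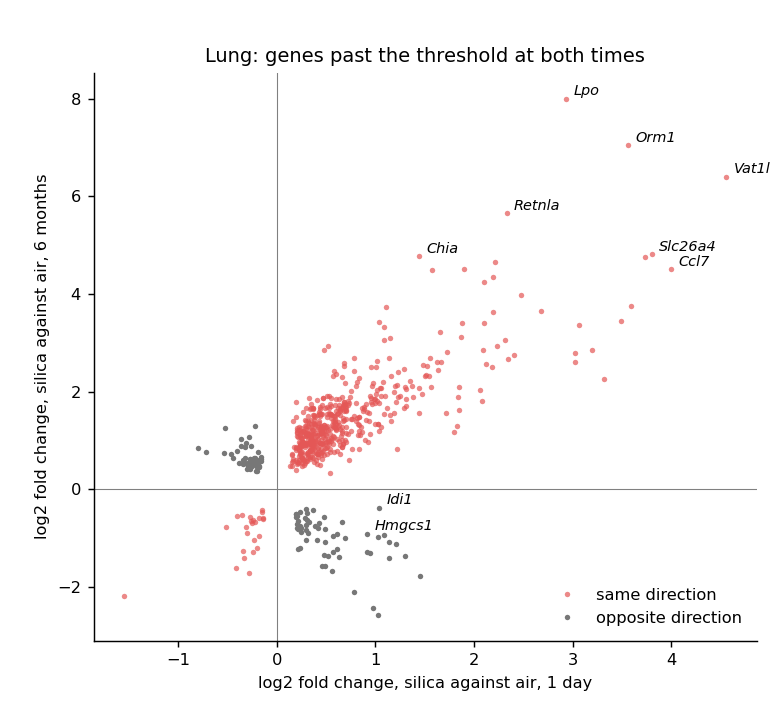
Log2 fold change of silica over air in lung at 6 months against that at 1 day for the genes past the threshold at both times that have a symbol and not only an ID. Red points changed in the same direction and grey points in opposite ones. With genes that have only an ID included, 575 changed in the same direction. Lpo is the highest point at 8.0 and Vat1l the farthest to the right at 4.56.

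In blood, no gene of the 12264 tested differed in its silica effect between times by edgeR, with 335 at an unadjusted p under 0.05 (539 without silica library 36 of 6 months). DESeq2 gave 1, Cdh2 (a name chosen after its values were seen), and limma 0. Without TMM factors, Cdh2 was at 101 CPM in blood air library 25 of 6 months and at most 2.22 in other blood. Its DESeq2 difference of -21.6 ± 3.34 (SE) is thus not read as the size of an effect. With no blood gene past the threshold at either time, the lists called in blood shared 0 genes with each other and 0 with those in lung; by DESeq2 Ifitm6, and by limma Ifitm6 and Sytl2, were shared by lung and blood at 6 months. The B cell and plasma cell list (median 0.50), platelet markers (0.27) and erythroid genes (0.52) passed camera with adjusted p-values of 0.00477, 0.00477 and 0.0311, and each had adjusted p = 0.936 with an estimated correlation.

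The silica effect was also compared between tissues, as blood minus lung. At 1 day 31 of 16148 genes passed, 3 with a more positive and 28 with a more negative effect in blood. Cxcl6 was at 1.17 ± 0.298 CPM in silica and 1.49 ± 0.670 in air blood (SD, n = 6 each) while it rose in lung, a difference of -3.97 ± 0.41 (SE, adjusted p = 1.79e-05). The differences were -5.01 ± 0.75 for Vat1l, -3.76 ± 0.67 for Orm1, -3.56 ± 0.59 for the macrophage-derived chemokine gene Ccl22 and -3.24 ± 0.41 for Ccl2. Chi3l1 (-1.21 ± 0.17) and Sod2 (-1.17 ± 0.16) passed as well. Ass1, which encodes argininosuccinate synthase (1.11 ± 0.17, adjusted p = 0.00251), Pla2g15 (0.75 ± 0.14) and Mylip (0.68 ± 0.13) had more positive effects in blood. Chemokines (median -1.31, adjusted p = 3.75e-06 with an estimated correlation), acute-phase genes (-0.86, adjusted p = 0.00159) and cholesterol synthesis genes (-0.56, adjusted p = 0.00260) passed both settings of camera, with 4, 2 and 1 genes past the threshold downward and 5, 4 and 8 adjusted over the list alone. Oxidative stress genes (-0.22, adjusted p = 0.0454) and alveolar type 1 cell markers (0.45, adjusted p = 0.0420) were the other lists that did. The acute-phase and type 1 lists had too few members past the filter in blood alone, so their differences include genes with few blood counts. Without blood silica library 11, 123 genes passed; without lung air libraries 06, 05 or 02-07, 15, 17 and 18 did, and without lung silica library 12, 19. Orm1 (adjusted p = 0.0501) and Mylip (0.0883) did not pass without lung air library 06, nor Pla2g15 (0.0831) without lung air library 05.

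At 6 months 193 of 16447 genes differed in their effect between tissues, 101 more positive and 92 more negative in blood, where the median difference over all genes was -0.14. In fitted differences, from which that median was not subtracted, Vat1l (-6.43 ± 0.74, adjusted p = 0.000402), Cxcl11 (-6.81 ± 1.61), Orm1 (-5.46 ± 0.68), Cxcl6 (-4.29 ± 0.64), Lcn2 (-3.60 ± 0.66), Ccl2 (-3.49 ± 0.58), Chi3l1 (-2.31 ± 0.50) and Sod2 (-1.44 ± 0.34) had more negative effects in blood. Clec4b2 (adjusted p = 0.0362) also passed downward, with counts of 0 in both air lungs. The monoamine transporter gene Slc18a2 (2.81 ± 0.33, adjusted p = 0.000402), Sh2d1b2 (3.48 ± 0.46), the mast cell protease gene Mcpt9 (2.81 ± 0.63), Reep2 (2.38 ± 0.44) and the thymidine kinase gene Tk1 (2.36 ± 0.55) had more positive ones. Sh2d1b2 was at 4.70 ± 3.02 CPM in air and 0.530 ± 0.251 in silica lungs (SD, n = 2 and 5), and Tk1 at 32.2 ± 3.48 and 8.38 ± 3.4. Of 18 lists that passed camera, none passed with an estimated correlation, where the smallest adjusted p was 0.0716. Without lung air library 19-24, 3 genes passed, Orm1, Slc18a2 and Vat1l (names chosen after their values were seen), and Mcpt9 was at 1.12. Without lung air library 20-25, 46 passed, and 97 did without lung silica library 34, 124 without blood air library 27, 388 without lung silica library 30-31 and 1257 without blood air library 25. Sod2 and Cxcl11 no longer passed in 14 of the 19 fits that each left out 1 library, Clec4b2 in 13, Tk1 in 12 and Mcpt9 in 8, and Cxcl11 was at -10.68 without lung air library 20-25.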

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

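All tests of an explanation below, and the other splits of the libraries, were chosen after the results they bear on were seen. In 13 of the 137 groups of 4 to 10 libraries examined, 1 library lay apart from the rest of its group by Dixon's criterion, where chance gives about 1 in 20 groups. The ratio after each value is the gap to the nearest library over the range of the group.

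In the lung at 1 day, air library 04-08 had the highest Mmp12 (12.0 CPM against 4.76 in the next, ratio 0.973) and Car12 (7.39 against 2.09, 0.871). Air library 02-07 had the highest Kcnh4 (3.69 against 3.44, 0.986) and Hp (52.6 against 46.2, 0.8293). Silica library 15 had the highest Dlk1 (23.7 against 13.5 CPM, 0.657) and Hp (131 against 115, 0.773). In the lung at 6 months, silica library 30-31 had the highest Shank1 (0.785 against 0.177 CPM, 0.775) and silica library 33 the highest Timp1 (53.1 against 35.2, 0.723). In blood at 6 months, air library 25 had a TMM factor of 1.93 against 1.09 (0.822), with the lowest Chi3l1 (130 against 318 CPM, 0.631) and Sod2 (67.0 against 131, 0.759). Air library 20 had the highest Ccl2 (3.28 against 1.47 CPM, 0.802), and silica library 36 the lowest total count (12.1 M against 14.3 M, 0.6625).

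The silica effect differed between 1 day and 6 months in lung for 4436 genes, and between blood and lung for 31 genes at 1 day and 193 at 6 months, by tests of the difference itself. Other splits of the libraries were not drawn for the time difference in lung or the tissue difference at 6 months, which include the air group of 2 lung libraries. Of 50 splits drawn for the tissue difference at 1 day, 1 gave as many genes, the real one. The highest other count was 1, which argues against chance. For lung at 1 day, 1 of 100 splits drawn reached 1836 genes and another gave at most 3, which argues against chance too. For lung at 6 months only 21 splits are possible, of which 1, the real one, reached 3189 genes and another gave at most 6. A share of 1 in 21 is the smallest that could arise there, so chance is argued against but not excluded. The splits also cannot tell silica from anything else that sets the 2 air lungs of 6 months apart. In blood 0 genes passed in the real split by edgeR at either time, a count that every split reaches (100 of 100 at 1 day, highest other 1; 100 of 100 at 6 months, highest other 2; 50 of 50 for the time difference, highest other 0), so the splits decide nothing there.

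Genes of the NK and proliferation lists were lower in the silica lungs than in the air lungs at 6 months, with a median of -1.70 on the log2 scale over 37 genes. A single air library as the source is argued against by medians of -1.64 without air library 19-24 and -1.74 without air library 20-25, and less blood in the silica lungs, which needs erythroid genes at -0.5 or lower, by their median of 0.53 (quartiles 0.21 and 0.56; 1.12 without air library 19-24, 0.10 without 20-25, 0.33 without silica library 30-31), although that list did not pass camera. The silica lungs of 6 months lay at a median of 0.51 above the air lungs of 1 day (quartiles 0.29 and 0.75), and the air lungs of 6 months at 2.38, so the pattern is consistent with high air lungs at 6 months. A candidate explanation is circulating granular lymphocytes in the air rats, since large granular lymphocyte leukaemia is a known disease of aged Fischer 344 rats. Blood air 25 was picked for the highest NK marker level in blood. In it, 53 genes were at 10 CPM or more and at least 8-fold above every other blood library. Of these, 39 (73.6%) were above all other lung libraries in both air lungs, against 3151 of 14983 lung genes (21%). Fisher's exact test, one-sided, gave p = 3.25e-16, over genes that are not independent. The air lungs stood out by the same markers, so some excess is expected whatever made these samples rich in NK genes. The test thus cannot decide the cause. These CPM were scaled to total counts alone. TMM factors would lower the values of air 25 (factor 1.93), and the set was not redrawn with them. Blood air 19, 20 and 25, which share numbers with these air lungs, were at a mean log2 CPM of 5.24, 6.31 and 7.53 for the NK markers. The other air blood of 6 months was at 5.30 to 6.09, and silica blood at 4.62 to 6.05 at 6 months and 4.41 to 6.32 at 1 day. Only air 25 thus lay above all other blood, and air 19 was the lowest air blood of 6 months. A number is not known to mark the same rat. A batch of the 6-month lungs that acts on the air rats alone and a biological loss of these cells after silica also stay open, as untested.

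The 5 close pairs of lung libraries differed in at most 9.30% of genes, where the closest other lung pair differed in 21%, which is consistent with the same RNA or library being sequenced under both numbers. Cage mates or like rats stay open: in blood, 0 of the 4 pairs of the same numbers were the closest of their group, but a number is not known to mark the same rat in both tissues, so this decides nothing.

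All 15 cholesterol synthesis genes rose in the silica lungs at 1 day, with a median of 0.65 and quartiles of 0.52 and 0.75. With RLE factors 15 of 15 still passed (median 0.65), so the rise does not depend on the choice between RLE and TMM factors. Both methods take most genes as unchanged, so this cannot exclude an error in scaling that they share. A larger share of alveolar type 2 cells is argued against by the lower median of their genes, 0.23 (quartiles 0.07 and 0.47). The time of day at which rats were killed could shift sterol genes, and it cannot be told apart from silica, since 2 of 12 clock genes passed, too few to argue for it and too many to exclude it. An effect of silica on sterol synthesis stays open.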

How the results depend on the processing

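Alternatives chosen after seeing the data were near-identical libraries as separate samples, fits without libraries that stood apart, and the silica lungs of 6 months against the air lungs of 1 day. The cause was not tested for the changes below, except where fewer libraries or a further threshold give it by construction. RLE factors, no filter on low counts and, in the silica and air comparisons, counts without erythroid genes left each count of genes within 1.5 times its value. The lung count at 1 day, 1836, was 594 with all 4 lung groups in 1 fit, 415 with a further threshold of 1.5-fold, and 1188 to 2240 with each library left out in turn. The lung count at 6 months, 3189, was 5812 by limma with sample weights, 6499 with all 4 groups in 1 fit, 6396 with near-identical libraries as separate samples and 56 to 4171 with each library left out in turn. It was 4308 against the air lungs of 1 day. For blood at 6 months, with 0 genes by edgeR and 720 at an unadjusted p under 0.05, DESeq2 gave 7, limma 5 and the fits with a library left out 0 to 2. Blood at 1 day stayed at 0 in each alternative. The time difference in lung ranged from 1642 to 5570 with each library left out, and in blood DESeq2 gave 1 gene, Cdh2, and the fits with a library left out 0. The genes shared by both times in lung, 575, became 241 with the 1.5-fold threshold and 936 with near-identical libraries as separate samples. For genes shared by lung and blood at 6 months DESeq2 gave 1 (Ifitm6) and limma 2 (Ifitm6 and Sytl2).

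The tissue difference at 1 day, 31 genes, became 135 by DESeq2, 200 by limma, 50 with near-identical libraries as separate samples, 123 without the blood library that stood apart, and 15 to 123 with each library left out. At 6 months, 193 genes became 797 by DESeq2, 2329 by limma, 797 with near-identical libraries as separate samples, 1318 without the blood libraries that stood apart, and 3 to 1257 with each library left out. With the replicate number as a replicate block in the libraries whose number occurs in both tissues, 4 genes passed at 1 day (Ccl2, Cxcl6, Muc20 and Rhbdl2) and 4 at 6 months (LOC103689945, Orm1, Slc18a2 and Vat1l), against 14 and 15 in the same libraries without the block. Names outside the rule were chosen after their values were seen. Both of these fits kept near-identical lung libraries as separate samples, unlike the counts of 31 and 193. Of 17 lung and blood pairs of the same number, 2 correlated best with their own number and 2 had a correlation over 0.1 (range -0.10 to 0.29), so the samples share a number and are not treated as paired.

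Of the gene lists, 19 passed camera in lung at 1 day and 4 with an estimated correlation (18 by fry), 23 in lung at 6 months and 0 (24 by fry), 8 in blood at 1 day and 0 (0 by fry), and 11 in blood at 6 months and 0 (0 by fry). The airway secretory list in lung at 6 months turned its direction without air library 19-24 (adjusted p = 0.842; range 2.41e-06 to 0.842 with each library left out), and the erythroid list in blood at 6 months without the libraries that stood apart (0.882).

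Against the air lungs of 1 day, these lung genes of 6 months turned sign on the log2 scale: Aim1l 0.64, Arl14epl 0.11, Cd8a 1.03, Eomes 0.059, Galnt6 0.55, Gprc5a -0.25, Gzmf 0.66, Hmgcs1 0.30, Idi1 0.68, Itgax 1.13, Kif11 0.54, Mepe 1.74, Mier2 0.65, Mki67 0.70, Nkg7 0.16, Pdpn -0.22, Plb1 0.64, Prf1 0.34, Pycard 0.64, Scn3b 0.48, Tdrd1 1.55, Tgfb1 0.50 and Top2a 0.48. Of these, Galnt6, Gprc5a, Hmgcs1, Idi1, Itgax, Pdpn, Pycard and Tgfb1 passed there, and the others did not. With each library left out in turn, Col1a1 in lung at 6 months ranged from -0.062 (without air 19-24) to 0.84. In the time difference, which Ccl2, Cxcl1, Spp1 and Mmp12 did not pass, Ccl2 ranged from -0.49 to 0.63, Cxcl1 from -0.028 to 0.61 and Spp1 from -0.82 to 0.18. The lowest value of Ccl2 and Cxcl1 and the highest of Spp1 came without air 19-24, and the opposite ends without air 20-25. Mmp12 ranged from 0.24 without air 04-08 of 1 day to 1.39 without air 20-25. Among the values of named lung genes over all alternatives, 1016 kept their direction and side of the threshold at 1 day, 84 lost the threshold and 4 gained it, and at 6 months 1091 kept both, 165 lost it and 24 turned sign. Depth limits the genes near the floor, which is 0.122 to 0.282 CPM before TMM scaling. Examples are Vat1l in air lungs at 1 day (0.153 CPM) and Orm1 in air lungs at 6 months (0.207 CPM), whose folds are uncertain.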

Other observations

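The comparisons between times, and the genes named here, were chosen after the data were seen. They set lung libraries of 6 months against those of 1 day by edgeR over all 4 lung groups. Each time is a table of its own, so time after exposure, age and batch cannot be told apart here. Of 16567 genes, 734 rose and 863 fell from 1 day to 6 months in silica lungs, and 3725 rose and 3152 fell in air lungs. Mast cell, basophil and eosinophil markers had the highest list median in silica lungs, 2.06 against -0.02 in air lungs, with 6 of 10 up and 1 down. The tryptase gene Tpsb2 rose by 3.23 ± 0.41 on the log2 scale (SE, adjusted p = 0.000581), carboxypeptidase A3 (Cpa3) by 3.04 ± 0.32, Mcpt2 by 2.78 ± 0.40 and the chymase gene Cma1 by 2.45 ± 0.38, while the stem cell factor receptor gene Kit fell by 0.71. Lipid-associated macrophage genes rose in 11 of 19 in silica lungs, with Spp1 at 3.46 ± 0.36 and Mmp12 at 1.51 ± 0.31. Spp1 was also at 3.89 ± 0.57 between the air lungs. T cell markers rose in 7 of 16, with the regulatory T cell gene Foxp3 at 1.22 ± 0.18 (adjusted p = 0.00107), and endothelial markers fell in 7 of 13 (median -0.34), with the VEGF receptor gene Kdr at -0.64 ± 0.12. Endothelial markers also fell in 8 of 13 and rose in 1 in air lungs (median -0.45). Clock genes fell in 6 of 12 and rose in 2 in silica lungs, and in air lungs 8 of 12 fell and 0 rose.

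In air lungs, NK markers rose in 13 of 16 and proliferation genes in 19 of 21, with Eomes at 3.79 ± 0.76 and Nkg7 at 3.15 ± 0.55. The T cell co-receptor gene Cd8a rose by 3.61 ± 0.60, whereas 8 of the 16 T cell markers fell. B cell and plasma cell markers fell in 12 of 15, with the B cell receptor gene Cd79b at -3.42 ± 0.36 and Ms4a1, which encodes CD20, at -2.85 ± 0.32. Alveolar type 2 cell genes fell in 11 of 15 and type 1 cell markers in 10 of 13, against 0 and 4 in silica lungs. Eomes was at 299 and 292 CPM in the air lungs of 6 months and at most 53.7 in the other lung libraries. It was at 341 CPM in blood air library 25 against at most 31.1 in other blood. These CPM were scaled to total counts alone, without TMM factors.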
